A study of Xiphophorus maculatus x Xiphophorus hellerii with 32 samples.

How the data were processed

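The samples were skin and spontaneous melanoma dissected from 9-month-old backcross hybrids of the platyfish Xiphophorus maculatus and the swordtail Xiphophorus hellerii. Per the labels' protocols, tissue was homogenised frozen in TRI Reagent, RNA was extracted with chloroform and spin columns with an on-column DNase step, RNA integrity was scored before sequencing, and libraries followed standard Illumina protocols. Reads were aligned with GSNAP, per the submitters' processing notes, which give no version. The genome build, the counting program, the annotation and the treatment of reads that match both parental alleles are not given in the sources used here. The authors deposited 1 table of raw counts, whole numbers of reads per transcript model, with 20499 transcript rows and 32 library columns. Of these rows, 30 carry a gene symbol and the rest carry Ensembl-style platyfish transcript identifiers, which the files do not pair with gene names. Every identifier has the prefix XM_, whose meaning is not given in the sources used here, and it is left out below. All 32 columns were used.

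Tissue was taken from the labels. The sample titles name a fish by a number and a letter, for example 11949f, and the number is shared by several fish. What this number marks is not given in the sources used here, and it was treated as a possible brood or batch. Columns were matched to samples by title. One tumor column, whose name abbreviates a fish called 11960b, matched no tumor title, since the only tumor title left over reads 11969b. That column was used as a tumor library without a fish, and the skin of 11960b was used as a skin library without a partner. This left 16 skin and 16 tumor libraries, with 14 fish that had both.

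The pairing by fish comes from the titles and was checked before calls were compared. Deviations of log2 CPM (library-size-scaled counts, prior count 2) from the tissue mean correlated between the skin and the tumor of a fish with r from 0.421 to 0.774, across transcripts, which are not independent replicates. Between different fish r lay between -0.341 and 0.338, and each of the 14 skin libraries correlated best with the tumor of its own fish. No library repeated another: over 240 pairs of libraries of the same tissue, the lowest chi-square statistic per degree of freedom was 33.3, and 0 columns were identical. The replicates are different fish.

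Total counts per library ranged from 2578877 to 6977222, with a median of 5615644 in skin and 5741446 in tumor. Analyses were run in R 4.3.3. The comparison of tumor with skin used the quasi-likelihood F-test of edgeR 4.0.16 on the raw counts, with TMM scaling, the filterByExpr low-count filter, no block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 14542 transcripts, 20 of them with a symbol, and 411 rows held no count in any library. The same test was repeated within each title number that had at least 3 libraries per tissue. The difference between title numbers was tested as an interaction, and the fish term was tested jointly over all fish coefficients in a model with tissue and fish. CPM values in the text are TMM-scaled. SE is the standard error of a log2 fold change.

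Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no low-count filter, a stricter filter of at least 1 CPM in 16 libraries, the fish as a replicate block in the 28 paired libraries, those 28 libraries without the block, voom of limma 3.58.1 with the fish as a random effect (estimated correlation 0.684), removal of the 10 most abundant transcripts, the title number as a covariate, a test against a 2-fold change (glmTreat), and leaving out each library within the title numbers with 3 fish. Omission of the shallowest tumor library, omission of the tumor column without a matching title, and removal of the 10 most abundant transcripts from the fish test were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.

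The genes to be named were set by a rule fixed before the data were examined. It takes a short list of single genes, then the 5 highest and 5 lowest fold changes among rows with a symbol that pass the threshold, reach a mean count of 50 in the higher tissue and change the same way in all 14 pairs, then 2 members of each list among gene lists for pigment cells, signalling, other cell types, metabolism and handling, and for the fish term the 6 rows with a symbol and the smallest p. Of the single genes, only Xmrk matched a symbol. Of the 19 lists, the single-gene list included, that list and the handling list each matched 1 symbol (Xmrk and HSP90AB1) and the others matched 0, so the planned gene-set test, which needed 5 measured members, was not run. Since the tested rows with a symbol are few, the others are given as well, and these, like the 4 identifiers, were chosen after their values were seen. A name ending in 1of2 or 2of2 marks a copy of a gene. Reads of such rows may have been divided between the copies, and their values are uncertain for that reason.

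The edgeR fits with and without the fish block, the interaction and the fish test were tested on simulated counts with 200 transcripts changed in known directions and with fish that differed by an SD of 0.5 on the log2 scale. In the comparison of all 32 libraries without a block, 23.5% of the 2-fold and 89.5% of the 4-fold changes were recovered among 14368 transcripts. With no added SD between fish the shares there were 47.4% and 96.7% among 14424. In the 28 paired libraries they were 61.0% and 98.9% without the block among 14532, and 85.6% and 99.0% with it among 14533. Within title number 11949 without a block they were 1.02% and 50.5%, and with it 34.0% and 95.8%. The simulations of 32 libraries and of 11949 without a block used dispersions estimated without the fish, which already hold differences between fish, so the added SD counts these again and their recovery is understated. DESeq2, voom, the test against a 2-fold change and the Xmrk association were not simulated. Within 11935 and within 11963 without a block they were 0% for both sizes. With the block, 13.0% and 87.6% were recovered in 11935, where 13.3% of the calls were false, and 3.12% and 56.2% in 11963, where 9.52% were false. The fish test called 0 transcripts when no fish effect was simulated and 76.3% when one was. Random regroupings of the libraries numbered 100 for the comparisons of all libraries, of paired libraries and of 11949, 10 within 11935 and within 11963, 50 for the interaction and 40 for the fish term, each including the real one.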

Results

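RNA was sequenced from skin and from spontaneous melanoma of 9-month-old backcross hybrids between the platyfish Xiphophorus maculatus and the swordtail Xiphophorus hellerii. In this cross, known as the Gordon-Kosswig cross, some offspring develop melanoma from pigment cells that carry the Xmrk oncogene. The submitters state the aims as a profile of gene expression and a study of which alleles the hybrids inherited. There were 16 skin and 16 tumor libraries, and 14 fish contributed both tissues. Total counts ranged from 4239036 to 6673975 in skin and from 2578877 to 6977222 in tumor. The first principal component of log2 CPM carried 28.5% of the variance. It ran from -90.3 to 1.08 in skin and from -19.4 to 126 in tumor, so the tissues overlapped only at its middle.

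**Figure D1:**
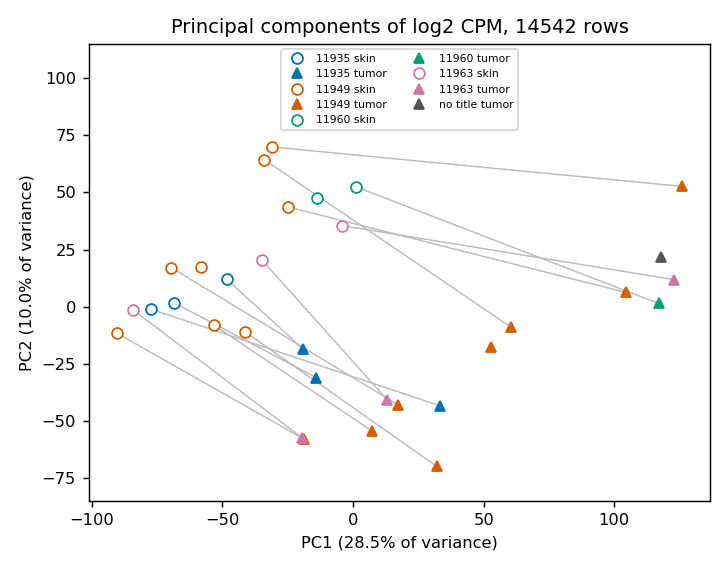
First and second principal components of log2 CPM for the 32 libraries (28.5% and 9.98% of the variance); circles are skin, triangles are tumor, colours are title numbers and grey lines join the libraries of a fish. In each of the joined pairs the tumor lies to the right of the skin.

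The first comparison asked which transcripts differ between melanoma and skin. Xmrk, a mutated duplicate of the epidermal growth factor receptor gene and the driver of these melanomas, averaged 67.1 ± 25.2 CPM in skin and 545 ± 247 CPM in tumor (SD, n = 16 each), an 8.11-fold difference (log2 fold change 3.02, SE 0.24, edgeR adjusted p = 1.55e-11). It was higher in the tumor of all 14 paired fish. The fold within a fish ran from 1.76 in 11935d to 22 in 11949h, with a median of 8.39. Skin was not free of Xmrk: its counts there lay between 105 and 771 per library. How reads were divided between Xmrk and the related receptor gene is not given in the sources used here.

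**Figure D2:**
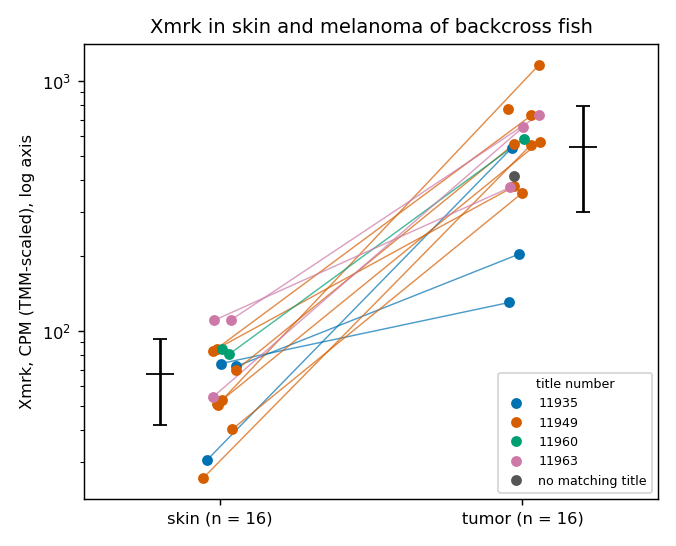
Xmrk in CPM (log axis) in 16 skin and 16 tumor libraries; lines join the libraries of a fish, colours are title numbers, and the black marks give the mean and SD of each tissue. The lowest tumor, at 130 CPM in fish 11935d, lay above the highest skin library, at 110 CPM.

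GSTM3, a glutathione S-transferase, rose 3.57-fold in tumor, from 81.1 ± 39.4 to 289 ± 180 CPM (SD, n = 16 each, log2 fold change 1.83, SE 0.29, edgeR adjusted p = 9.02e-06), and was higher in 14 of 14 pairs. AP1M1, a subunit of a clathrin adaptor complex, rose by 0.78 on the log2 scale (SE 0.20, adjusted p = 0.00332, edgeR), again in 14 of 14 pairs. STAT4, a cytokine-activated transcription factor, rose by 0.57 (SE 0.20, adjusted p = 0.0372, edgeR) and was higher in 11 of 14 pairs. Without the tumor of 11949f, the shallowest library, its adjusted p was 0.0542, the highest value over the alternatives, which began at 7.85e-04.

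HSP90AB1, a constitutive cytosolic chaperone, fell in tumor from 6454 ± 1789 to 3789 ± 591 CPM (SD, n = 16 each, log2 fold change -0.77, SE 0.13, edgeR adjusted p = 1.54e-05). It was lower in the tumor of all 14 pairs and ranked 14 among all rows by total count. It was the single measured member of the list for handling and heat shock. CHD4_2of2, a copy of the ATPase of a chromatin remodelling complex, fell by 0.79 on the log2 scale (SE 0.21, adjusted p = 0.00511, edgeR) and was lower in 14 of 14 pairs. GPX6, of the glutathione peroxidase family, fell by 1.08 (SE 0.24, adjusted p = 9.05e-04, edgeR) and was lower in 13 of 14. LDHB_1of2, a copy of a lactate dehydrogenase subunit gene, fell by 0.45 (SE 0.12, adjusted p = 0.00644, edgeR) and was lower in 11 of 14. CHD4_2of2 and LDHB_1of2 may share reads with their other copies.

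Of the 20 tested rows with a symbol, 8 passed the threshold, 4 higher and 4 lower in tumor, and 8 also when adjusted over these rows alone. With the fish as a block 10 passed, including all of these 8. The additional ones were CYP1A1, a xenobiotic-metabolising enzyme (log2 fold change -1.01, SE 0.38, edgeR adjusted p = 0.0383), and OXR1, a gene of oxidation resistance (0.34, SE 0.13, adjusted p = 0.0404). Without the block their adjusted p were 0.174 and 0.191, and over the alternatives they ran from 0.00129 to 0.234 for CYP1A1 and from 0.00776 to 0.234 for OXR1. The kinase genes MAPK9 (log2 fold change -0.12, SE 0.10), MAPK14_2of2 (-0.24, SE 0.14), PRKCB (0.60, SE 0.35) and PRKCE_1of2 (-0.05, SE 0.16) and the receptor FGFR4 (0.22, SE 0.28) did not pass in edgeR with or without the block. Neither did CALR3_1of2, CRY2, CSNK1A1, CUL4B or NR2F6_1of2. A further 10 symbols had too few counts for a test, among them PMEPA1 (41 counts over all skin and 151 over all tumor libraries), KISS1 (3 and 11) and IGF1 (21 and 30).

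**Figure D3:**
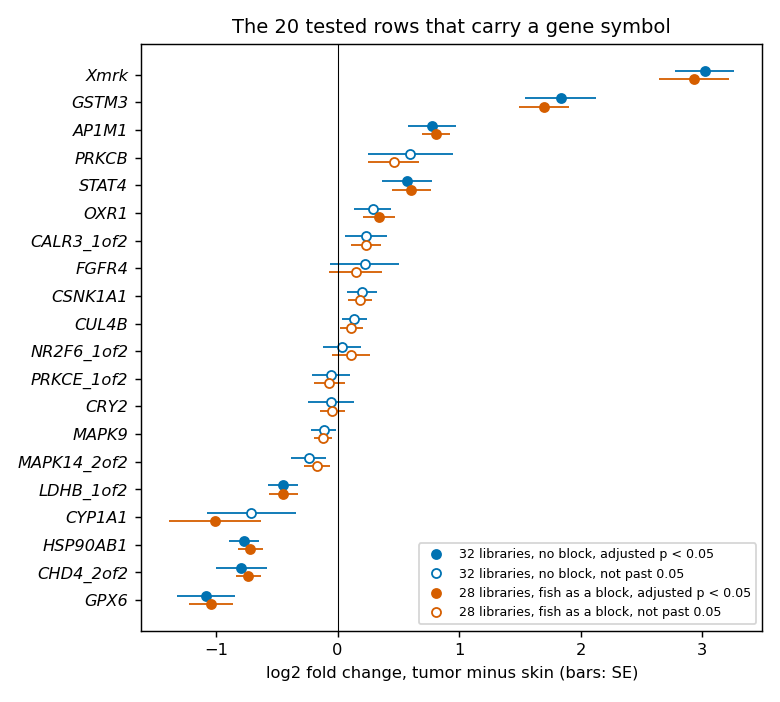
Log2 fold change, tumor minus skin, of the 20 tested rows with a gene symbol, with SE as bars; blue is the comparison of 32 libraries, orange that of 28 libraries with the fish as a block, and filled points have an adjusted p below 0.05. Xmrk at 3.02 and GPX6 at -1.08 mark the ends of the range.

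Over all 14542 tested transcripts, 3419 (23.5%) passed the threshold in edgeR, 1634 higher and 1785 lower in tumor. By estimated fold change, at least 2-fold changes among these calls numbered 851 higher and 946 lower, and at least 4-fold changes 279 and 255. Tested against a 2-fold change (glmTreat), 636 passed, 362 higher and 274 lower. Of the 3419 calls, 787 were higher and 852 lower in all 14 pairs, a tally over calls made on the same libraries and so not a separate test. The files do not pair the transcript identifiers with gene names. ENSXMAT00000012105 rose from 16.9 ± 16.1 to 2538 ± 1612 CPM (SD, n = 16 each, log2 fold change 7.23, SE 0.50), and ENSXMAT00000004603 from 8.81 ± 8.89 to 1476 ± 981 CPM (7.38, SE 0.55). ENSXMAT00000004916 fell from 67.4 ± 69.6 to 0.266 ± 0.443 CPM (-8.03, SE 0.68), and ENSXMAT00000003959 from 36.3 ± 32.4 to 0.186 ± 0.258 CPM (-7.52, SE 0.54). With the fish as a block, 6740 of 14591 transcripts passed, 3394 higher and 3346 lower, and these included 3390 (99.2%) of the 3419, of which 0 changed sign.

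The comparison was then repeated within the title numbers, which may mark broods or batches. In 11949, with 8 skin and 8 tumor libraries, Xmrk averaged 57.2 ± 20.6 CPM in skin and 635 ± 258 CPM in tumor (SD, log2 fold change 3.45, SE 0.31, edgeR adjusted p = 5.41e-07). In 11935, with 3 libraries per tissue, it averaged 58.9 ± 24.6 and 290 ± 218 CPM (2.30, SE 0.64, edgeR unadjusted p = 0.00928, adjusted p = 0.247), and the log2 fold change was 1.49 without the tumor of 11935f. The unadjusted p is given because Xmrk was named before the data were examined. In 11963, also with 3 per tissue, Xmrk averaged 91.6 ± 32.2 and 587 ± 188 CPM (2.71, SE 0.45, edgeR unadjusted p = 6.05e-04, adjusted p = 0.0660). With the fish as a block the adjusted p of Xmrk were 4.22e-05 in 11949, 0.102 in 11935 and 0.0232 in 11963.

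Within 11949, 1822 transcripts passed in edgeR, 849 higher and 973 lower in tumor, and 3982 with the block over 7 fish. Within 11935, 0 passed, while 1746 had an unadjusted p below 0.05, DESeq2 called 579 and the blocked edgeR fit called 1505 (618 higher, 887 lower). Within 11963, 58 passed (52 higher, 6 lower), 1356 had an unadjusted p below 0.05, DESeq2 called 620 and the blocked fit 1143 (654 higher, 489 lower). The count in 11963 was 0 without the skin of 11963a or 11963g or the tumor of 11963d or 11963g, and 3 without the skin of 11963d. In simulated counts 13.3% of the blocked calls in 11935 and 9.52% of those in 11963 were false. DESeq2 was not simulated. Of the 11949 calls tested in 11935, 1744 of 1762 (99%) had the same sign there, against 79.0% of all transcripts. In 11963 it was 1746 of 1786 (97.8%), against 74.6%.

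Whether the difference between tumor and skin itself differed between 11935, 11949 and 11963 was tested as an interaction. For Xmrk the edgeR interaction had an unadjusted p of 0.120, and 0.185 with the fish as a block, where the log2 fold changes of 11935 and 11963 lay -1.31 and -0.70 from that of 11949. Over all 14568 transcripts 0 passed the threshold in edgeR. An unadjusted p below 0.05 was seen for 84, where 728.4 are expected by chance, and DESeq2 also called 0. With the block 0 of 14416 passed and 868 had an unadjusted p below 0.05, where 720.8 are expected. In simulated data with interactions placed in 11963 alone, the test without the block recovered 0% of 2-fold and 0% of 4-fold interactions, and the blocked test 1% and 43.4%. The count of 0 without the block therefore does not bear on differences of these sizes.

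The last comparison asked how far fish differed from one another in both tissues, in a cross whose offspring inherit different sets of alleles. Among the rows with a symbol, CHD4_2of2 had the smallest p: its mean over the 2 tissues of a fish spanned 1.84 on the log2 scale, lowest in 11963a and highest in 11963g (edgeR adjusted p = 2.05e-04). AP1M1 spanned 1.62 (adjusted p = 4.36e-04), CRY2, a circadian clock repressor, 1.58 (adjusted p = 6.43e-04), and PRKCB, a protein kinase C gene, 3.35 (adjusted p = 0.00150), all in edgeR. GSTM3 spanned 2.63 (adjusted p = 0.00297) and CALR3_1of2, a calreticulin copy, 1.41 (adjusted p = 0.00964). Within the 7 fish of 11949 alone the adjusted p rose to 0.0721 for AP1M1, 0.0733 for GSTM3 and 0.173 for CALR3_1of2. Xmrk, with a span of 1.53, did not pass (adjusted p = 0.670).

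Over all 14591 transcripts, 11578 (79.4%) passed the fish test in edgeR. The median span of fish means was 2.12 on the log2 scale. Within the 7 fish of 11949 alone, 8045 of 14371 transcripts passed. In the paired libraries fish accounted for 66.7% of the variance of log2 CPM, tissue for 18.6% and the remainder for 14.7%. The fish share covers 14 fish and the tissue share 2 tissues, so their sizes are not directly comparable. With no difference between fish, the fish term would still take about as much as the remainder, and spans of fish means would still be above 0. Of the 20 tested rows with a symbol, 8 (40.0%) passed the fish test, against 79.4% of the identifiers (two-sided Fisher's exact test, p = 1.39e-04). Among 10000 random lists of identifiers matched on abundance, a median of 16 of the 20 passed, and 0.03% of the lists had as few. GPX6, CSNK1A1 and HSP90AB1 narrowly failed the threshold (edgeR adjusted p = 0.0508, 0.0520 and 0.0553). STAT4 and FGFR4 narrowly passed it (edgeR adjusted p = 0.0371 and 0.0400), so the size of the contrast depends on the threshold. Both comparisons treat transcripts measured in the same 14 fish as independent units.

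**Figure D4:**
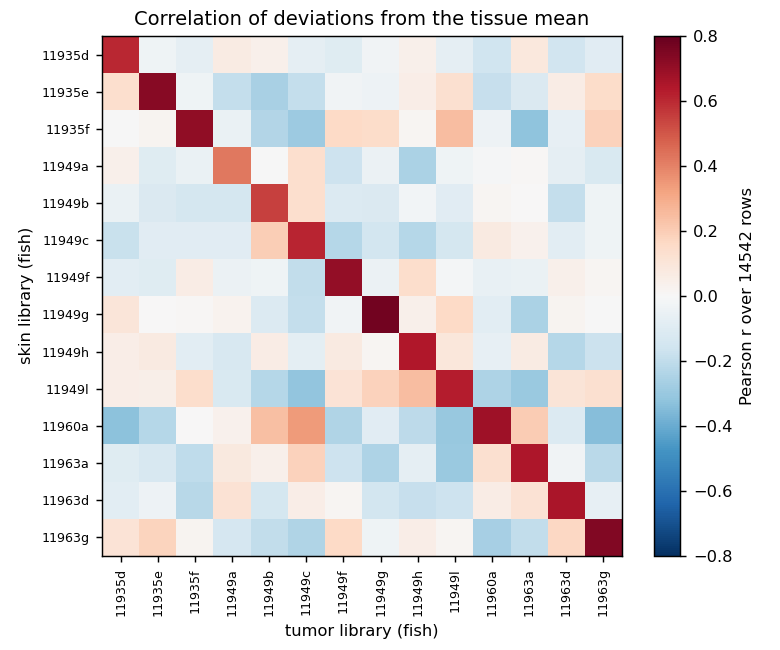
Pearson correlation over transcripts between deviations from the tissue mean, for each skin library (vertical axis) and each tumor library (horizontal axis) of the 14 paired fish. The diagonal, which joins the tissues of a fish, holds values from 0.421 to 0.774, and the other cells lie between -0.341 and 0.338.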

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

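The tests of identifier order, of the tumor column without a title and of regrouped title numbers were chosen after the results were seen, and the kurtosis test was chosen after example transcripts had been looked at. Libraries that stood apart were searched for in 42 groups of 8 libraries of 11949, where chance gives about 2.1 and 5 were found. The tumor of 11949f had a total count of 2578877, and the next lowest tumor of that title number had 4938279. CSNK1A1 in the skin of 11949a stood at 511 CPM, and the next highest skin library at 328. LDHB_1of2 stood at 2455 CPM in the skin of 11949a, with the next at 1566. PRKCE_1of2 stood at 10.7 CPM in the tumor of 11949c, below the next lowest at 22.1. STAT4 reached 11.4 CPM in the skin of 11949h, above the next at 6.66. In 60 comparisons of direction between title numbers, 0 had every fish of one title number moving against every fish of another.

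Most transcripts differed between fish in both tissues, and reads or tissue of one library present in the other of the same fish were tested first: at a median over fish, 3.41% of the skin level of the 20 most skin-specific transcripts was seen in tumor and 1.76% the other way, below the 25% set as the bound, with the highest values at 11.6% (11963d) and 19.9% (11935d), and the 9 fish under 5% both ways still had a median same-fish r of 0.646. Among 40 matchings of tumors to skins, 1, the real one, gave 11578 transcripts and the highest other gave 6. The same-fish correlations had already shown this pairing, so the count is not separate evidence. A hypothesis is that fish fall into classes by inherited parental alleles. For the 11510 transcripts called in the fish test, the median excess kurtosis over 14 fish was -0.881. In 1000 random rotations the mean was -0.255 and the lowest value -0.409 (rotation p = 0.001, the smallest they can give). A value this low is what 2 classes of fish would give. The rotations took no account of title numbers, so groups by brood or batch are not separated from classes of alleles. Transcripts 5 places apart in identifier order shared their fish pattern across tissues at a mean r of 0.0270, above the highest permuted value of 0.00784 (p = 0.001, the smallest possible), which is consistent with linked inheritance if the order follows position, a point not checked here. Inherited expression and an allele-dependent yield of counted reads may both give this, and handling shared by the libraries of a fish also stays open, because 0 fish had repeat libraries of a tissue.

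The tumor column without a matching title carries a name that abbreviates 11960b, while the tumor title left over reads 11969b. Its deviations from the tumor mean correlated with the skin of 11960b at r = 0.656, within the range of the paired fish, and with the next skin at 0.204. This suggests a mistyped title, as a hypothesis, and the column was not paired. No biological explanation was tested.

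The calls between tumor and skin were set against other groupings of the same libraries. For all 32 libraries 1 of 100 splits, the real one, gave 3419 transcripts, and the highest other gave 54. These splits ignored the fish and could place both tissues of a fish in the same group, which the real grouping never does. They show that free splits rarely give as many, but they do not test chance within the paired design. For the paired libraries with the fish as a block 1 of 100 swaps of tissue names within fish, again the real one, gave 6740, and the highest other gave 2777 while keeping the real names, or their mirror, in 12 of 14 fish. For 11949, 1 of 100 splits gave 1822, and the highest other gave 800 while keeping 14 of 16 names. The splits of 11949 also ignored the fish. For 11935 all 10 of 10 splits gave at least the real count of 0 (highest other 0), and for 11963 the real split alone, 1 of 10, gave 58 (highest other 0), and 10 splits are too few for a share under 0.05. For the interaction, in the blocked fit of 26 libraries, all 50 of 50 assignments of title numbers to fish gave at least the real count of 0, which a count of 0 fixes in advance, and the highest other gave 317.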

How the results depend on the processing

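Omission of the tumor of 11949f, omission of the tumor column without a title and removal of the 10 most abundant transcripts from the fish test were chosen after the data were seen. Of the counts and differences that answer a comparison, 19 alternatives stayed within 1.5 times of a value above 0 and 14 moved further. A further 12 gave 0 beside a reported 0 (8 in 11935, 4 for the interaction), which shows no stability. The count between tumor and skin was 3419 as reported, 2779 in the 28 paired libraries without the block and 6740 there with the replicate block. It was 7272 with voom and a random fish effect, which changes the test as well. Testing against a 2-fold change left 636, by its stricter null. With the replicate block the count was 3982 in 11949, 1505 in 11935 and 1143 in 11963, and with DESeq2 it was 2820, 579 and 620. Leaving out single libraries gave 0 to 43 in 11963 and 0 throughout in 11935. In the same 28 libraries the block alone changed 2779 to 6740, since differences between fish stay in the error of the unblocked fit. Simulated 2-fold changes there were recovered at 61.0% without the block and 85.6% with it. The blocked fits of 11935 and 11963 also used the same libraries as the unblocked ones. In simulated counts 13.3% of the blocked calls in 11935 and 9.52% of those in 11963 were false. The cause of the other moves was not tested apart from the construction of each fit.

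For single genes, 261 alternatives kept direction and side of the threshold, 9 moved a gene past it, 4 moved one below it, and 0 reversed a call. The fish-test alternatives among these have no direction, so for them only the side of the threshold was compared. Gains were seen with voom for CALR3_1of2, CSNK1A1, CYP1A1 and OXR1, with the replicate block for CYP1A1, OXR1 and Xmrk in 11963, and with DESeq2 for Xmrk in 11935 and 11963. Losses were STAT4 without 11949f and, in the fish test within 11949, AP1M1, GSTM3 and CALR3_1of2. The paired fit changed no other call. Over all title numbers together the Xmrk log2 fold change ran from 2.93 to 3.05. The gene-set alternatives were not run, since 0 lists had enough members. At this depth 10 symbols had too few counts for a test.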

Other observations

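The looks at skin signal, at tumor-specific transcripts and at tumor calls beside Xmrk were chosen after the association was seen, the other tests before. Fish with more Xmrk in the tumor were examined for tumors farther from their own skin. Over 14 fish, the root mean square log2 difference between the tissues of a fish had r = 0.426 with log2 CPM of Xmrk in its tumor (permutation p = 0.127, adjusted over 4 tests 0.509) and rho = 0.270 (permutation p = 0.347, adjusted 0.695). Without the 2 tumors farthest from the median in Xmrk, 11935d and 11935e, r was -0.268, and within the 7 fish of 11949 it was -0.097, so the relation cannot be told from none with 14 fish. Xmrk in skin and in tumor of the same fish had r = -0.137 (permutation p = 0.644, adjusted 0.772) and rho = 0.0857 (permutation p = 0.772, adjusted 0.772). For this relation r was -0.0873 without the 2 fish farthest from the median in skin Xmrk, 11949l and 11935f, and 0.0579 within 11949.

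Over the 16 tumors, 95 transcripts were associated with Xmrk in edgeR, 88 positively and 7 negatively. This was the highest of 60 assignments of the Xmrk values to tumors: 1 of 60, the real one, gave as many, and the highest other gave 4. The count of 95 depended on 11935d and 11935e, whose tumors held 130 and 203 CPM of Xmrk: without them 2 transcripts passed. Their removal also narrowed the range of Xmrk and left fewer tumors, and this loss of power was not separated. Fish 11935d and 11935e both carry title number 11935, which the assignments did not hold fixed, so a brood or batch effect of that number is not separated from low Xmrk, though the tumor of 11935f held 539 CPM. As a hypothesis, these tumor samples may hold less melanoma, or the Xmrk level of the tumor cells may be lower, and the data do not separate these from each other or from the title number. Skin signal in the tumors does not settle it: the tumor held 9.32% of the skin level of skin-specific transcripts in 11935d and 8.70% in 11935e, but also 11.6% in 11963d (732 CPM of Xmrk), 7.38% in 11963g (653 CPM) and 6.25% in 11949h (1162 CPM). In the other direction, the skin of 11935d held 19.9% of the tumor level of tumor-specific transcripts and that of 11935e 4.07%. The next highest was 3.53% in 11963a. The root mean square differences between the tissues of 11935d and 11935e, 0.703 and 0.792, were the smallest, with 0.880 next in 11949f. Their tumors thus lay closer to skin as a whole, which does not tell these explanations apart. Of the 88 positively associated transcripts, 80 were called higher in tumor than in skin, against 12.8% of the 11713 transcripts tested in both fits. These calls rest on the same tumors, and this share does not tell the explanations apart either.

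Tumors were examined for a wider spread between fish than skin. The mean variance of log2 CPM over transcripts was 0.742 in skin and 0.886 in tumor, a difference of 0.145, and 710 of 8192 swaps of the tissue names within fish gave one as large (exact permutation p = 0.0867), so chance is not excluded. Of the transcripts, 46.5% varied more between tumors than between skins.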
